A study of Macaca fascicularis with 6 samples.

How the data were processed

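Total RNA from liver of 6 cynomolgus macaques, 3 given vehicle and 3 given an LXR ligand, had been extracted with a silica column kit, labelled with biotin and hybridised to Affymetrix arrays, 1 animal on each array, per the labels and the submitters' design text. The group of each array was taken from its title and treatment label. The probe annotation names the platform as a human array, so macaque transcripts were read by human probes and sequence differences between the species can lower a probe set's signal. The deposited values are intensity values on a linear scale, MAS5 signals per the submitters' processing notes, with the version, scaling target and any filter not given in the sources used here. In the values themselves, the 2% trimmed mean was 499.9 on every array, signals ran from 0.165 to 237196, and no log had been taken. Detection calls were not used here, so a dim probe set cannot be told from an absent transcript.

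Of 54675 probe sets in the annotation used here, 41097 had 1 gene symbol, 1801 several and 11777 none, controls included. No gene was named from a probe set with several symbols. Some of the genes listed beforehand had no probe set named in this annotation and were not analysed here, among them 3 of the 13 genes in the first part of the naming rule below. Of the 13349 human symbols tested, 11851 (88.8%) also occur as a symbol in the macaque gene annotation of assembly T2T-MFA8v1.1, which was used for names only. No coordinates are given, since the files carry none.

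Values were transformed to log2(signal + 16), with the scaling between arrays kept as deposited. Fold changes are on this scale and understate the change of dim probe sets. The 62 control probe sets were left out, and the 27304 probe sets whose mean signal over the 6 arrays was at or above the median of all means, 129, were tested: 22564 with 1 symbol, 1032 with several and 3708 with none. Tests were two-sided, by lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, on all 6 arrays without covariates, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The prior contributed 6.23 degrees of freedom, and the median SE of a log2 difference was 0.35. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

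Before the data were examined, 24 gene lists were fixed from general knowledge of LXR and liver biology, 13 of pathways and 11 of cell types, with 326 distinct genes, of which 262 were measured, meaning that a tested probe set with 1 symbol named them. Some genes stand in more than 1 list. A gene was represented by its brightest probe set among those with 1 symbol. The 20 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists. Members were also counted with p adjusted over the list alone. With an estimated correlation in camera, 0 lists passed and 3 had an unadjusted p under 0.05. In fry's directional test 0 passed and 3 had an unadjusted p under 0.05, while 4 passed in camera with the preset correlation and 6 in fry's test for change in either direction: LXR targets, fatty acid and triglyceride synthesis, lipoprotein receptors, acute phase, macrophage markers and endothelial markers. Camera asks whether a list's genes rank differently from other genes, fry whether they move on balance one way, and neither of fry's tests compares the list with other genes.

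Genes were named by a rule also fixed beforehand. It took 13 LXR and sterol genes whatever their values, the 10 higher and 10 lower probe sets with 1 symbol and non-overlapping groups that passed, filled up by smallest p where fewer passed, and up to 4 members of each list by smallest p. No probe set passed, so the smallest p filled all 20 places. RNA quality was compared by an exact two-sided permutation test of the log2 ratio of 3' to 5' control probe sets.

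The tests were run on simulated data with the real means and spread, 10 simulations of 27304 probe sets in which 50 were changed at each size. The share called was 3.4% at a log2 change of 1, 37.6% at 2, 64.4% at 3 and 70.8% at 4, with 0.0140% of unchanged probe sets called. In 10 simulations of 13349 genes with the LXR list shifted by 0.7, camera called that list in 10 with the preset correlation and in 8 with an estimated correlation. Among the lists not shifted, 3 of 180 tests were called with the preset correlation and 0 of 180 with an estimated correlation. The simulated genes were independent, so these shares leave out correlation between genes.

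Alternatives fixed beforehand were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a stricter filter, eBayes without the trend and with robust estimation, array weights, the replicate number as a block, leaving out each array, a threshold of 0.10, 1 probe set per gene, an estimated correlation, fry, the mean of a gene's probe sets, and the other probe sets of each named gene. Lists without their leading members were added after seeing the data. All 6 arrays were used, and 4 further gene lists served for the closing observations.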

Results

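Gene expression was measured in liver tissue of 6 cynomolgus macaques (Macaca fascicularis) with Affymetrix arrays, with 1 animal on each array per the submitters' design text. Vehicle had been given to 3 animals and a ligand of the liver X receptor (LXR) to the other 3. LXR is a nuclear receptor that senses oxidised cholesterol and switches on genes of sterol efflux and of fatty acid synthesis. The titles of the ligand arrays carry the letters GW, which the sources used here do not explain, and these sources did not otherwise give the identity of the ligand, its dose or the length of treatment. The arrays carried 54675 probe sets designed against human transcripts, so each macaque gene is named by the human symbol of its probe set. The median MAS5 signal of an array, an intensity in arbitrary units, was 111, 138 and 139 on vehicle arrays 1 to 3 and 132, 129 and 139 on ligand arrays 1 to 3. Across tested probe sets, which are not independent replicates, Pearson's r between arrays was 0.903 to 0.919 within a group and 0.900 to 0.922 between groups, 2 overlapping ranges. On the first principal component, with 23.0% of the variance, ligand array 1 stood apart at -89.8, with the other 5 arrays at 0.632 to 36.8. With 3 arrays in each group, the number of animals limits the precision of every value.

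The design asked which liver genes differ between animals given the LXR ligand and animals given vehicle, and the known targets of the receptor were examined first. SREBF1, a transcription factor that drives fatty acid synthesis genes, rose 5.93-fold, from a mean signal of 429 ± 104 (SD, n = 3) with vehicle to 2855 ± 1369 (SD, n = 3) with the ligand. ABCG1, a transporter that moves cholesterol out of cells, rose 2.48-fold, from 338 ± 36.3 to 866 ± 105 (SD, n = 3 per group). MYLIP, a ubiquitin ligase that marks lipoprotein receptors for breakdown, rose 2.56-fold, from 493 ± 102 to 1329 ± 452 (SD, n = 3 per group). The 19 measured LXR targets, of 22 listed before the data were examined, rose as a group, with a median 1.56-fold higher signal and 16 of the 19 genes higher. As a competitive test with a preset correlation, limma's camera gave the list adjusted p = 3.65e-08. The list did not pass with an estimated correlation in camera (adjusted p = 0.198) or in the directional test of fry, a self-contained tool (adjusted p = 0.0914), but passed in fry's test for change in either direction (adjusted p = 0.0179). Its estimated correlation was 0.088, above the preset 0.01.

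In limma's moderated test on log2(signal + 16), the scale of all fold changes given here, the log2 differences were 2.57 ± 0.39 (SE) for SREBF1, 1.31 ± 0.25 for ABCG1 and 1.36 ± 0.32 for MYLIP. These 3 genes passed when limma's p was adjusted over the list alone, at adjusted p = 0.00111, 0.00325 and 0.00954, with all 3 ligand arrays above all 3 vehicle arrays for each. The other 16 measured members did not pass, and 0 of the 19 passed with adjustment over all probe sets tested, where the limma adjusted p of SREBF1 was 0.370 and 7 had an unadjusted p under 0.05. Without vehicle array 3, 8 of the 19 passed over the list alone.

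Several further LXR targets had higher mean signals with the ligand without passing. ABCA1, the transporter that loads cholesterol onto apolipoprotein A-I, had a mean signal of 1805 ± 583 with vehicle and 2989 ± 397 with the ligand (SD, n = 3 per group), a log2 difference of 0.77 ± 0.27 (SE). PLTP and CETP, which exchange lipids between lipoproteins, had log2 differences of 0.85 ± 0.31 and 0.64 ± 0.25 (SE). FASN, the fatty acid synthase, had a log2 difference of 0.69 ± 0.26 (SE), and SCD, a desaturase of fatty acids, 1.31 ± 0.67 (SE). ABCG5 and ABCG8 form the transporter that secretes cholesterol into bile, and their log2 differences were 0.52 ± 0.27 and 1.12 ± 0.55 (SE). Single arrays weighed on these values: SCD ran from 0.51 without ligand array 1 to 2.04 without ligand array 3, ABCG8 from 0.39 without vehicle array 3 to 1.53 without vehicle array 2, ABCG5 was 0.21 without vehicle array 3, ABCA1 0.48 without vehicle array 1 and CETP 0.39 without ligand array 1. NR1H3, which encodes LXR alpha, had a log2 difference of 0.11 ± 0.23 (SE), less than its error. Other probe sets of a gene did not always behave alike: a second SREBF1 probe set had a log2 difference of -0.60, a second FASN probe set -0.22, and the remaining ABCG1 probe sets 1.39, 0.52 and 0.043. The 4 tested MYLIP probe sets were all higher with the ligand, as were the 2 tested SCD probe sets.

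**Figure D1:**
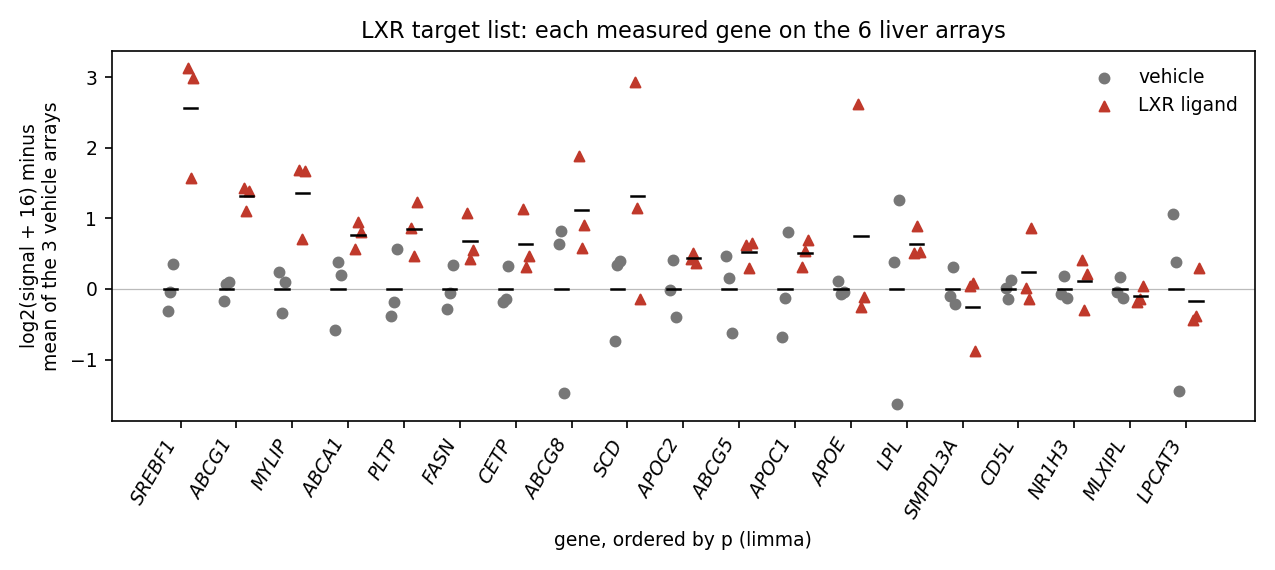
Log2(signal + 16) of each measured LXR target on each of the 6 liver arrays, relative to the mean of the 3 vehicle arrays, with genes ordered by limma p, circles for vehicle, triangles for the LXR ligand and bars at group means. The SREBF1, ABCG1 and MYLIP ligand arrays all lie above the vehicle arrays, with mean differences of 2.57, 1.31 and 1.36, while NR1H3 differs by 0.11.

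Among genes of fatty acid and triglyceride synthesis, 13 of the 21 measured genes were higher and 8 lower with the ligand. With limma's p adjusted over the list alone 3 passed, and none passed with adjustment over all probe sets tested. SREBF1 rose, as given above. ELOVL5, an elongase of polyunsaturated fatty acids, rose 2.03-fold, from 2410 ± 850 to 4687 ± 332 (SD, n = 3 per group), at limma adjusted p = 0.0405. Its limma adjusted p over all probe sets was 0.773, and of its 4 tested probe sets 3 were higher and 1 lower. LPIN1, a phosphatidate phosphatase of triglyceride synthesis, fell 1.87-fold, from 2238 ± 578 to 1179 ± 226 (SD, n = 3 per group), also at limma adjusted p = 0.0405, although its other tested probe set had a log2 difference of 0.14; a further one, too dim to be tested, had -0.92. The list as a whole, with a median log2 difference of 0.24, did not pass in camera (adjusted p = 0.109). Without ligand array 1 its median was -0.054, and without ligand array 2 it was 0.44 and the list passed (camera adjusted p = 0.0225).

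The other sterol and lipoprotein lists gave no call in camera. In cholesterol synthesis, 9 of 19 measured genes were higher and 10 lower, none passed, the median log2 difference was -0.019, and camera gave adjusted p = 0.616. TM7SF2, a sterol reductase, had the smallest p of that list, with a log2 difference of -0.34 ± 0.21 (SE). In the list of lipoprotein receptors and their control, 5 of 10 genes were measured. MYLIP rose and SORL1, a sorting receptor related to the lipoprotein receptors, fell 1.97-fold, from 10028 ± 3893 to 4926 ± 1461 (SD, n = 3 per group), at limma adjusted p = 0.0324 adjusted over the list alone, with overlapping groups. That list had a median log2 difference of 0.22 and camera adjusted p = 0.534. Of 21 measured apolipoproteins and remodelling factors, 12 were higher and 9 lower, none passed, and the median log2 difference was 0.046 (camera adjusted p = 0.471).

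Bile acid genes also went both ways, with 11 of 20 higher, 9 lower, none passing, a median log2 difference of 0.050 and camera adjusted p = 0.827. NR0B2, a repressor in the feedback on bile acid synthesis, had a log2 difference of 0.83 ± 0.30 (SE), and CYP8B1, the sterol hydroxylase that sets the share of cholic acid, -0.49 ± 0.21 (SE). CYP7A1, the rate-limiting enzyme of bile acid synthesis, was too dim to be tested, with signals of 57.0, 114 and 128 on the vehicle arrays and 60.1, 38.5 and 64.3 on the ligand arrays. In fatty acid oxidation, 12 of 22 genes were higher and 10 lower, none passed, and the median log2 difference was 0.10 (camera adjusted p = 0.757). PPARA, the receptor that drives fatty acid oxidation genes, had the smallest p there, with a log2 difference of -0.52 ± 0.21 (SE).

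Of 13 measured genes of glucose production and handling, 10 were lower and 3 higher with the ligand, with a median log2 difference of -0.14. The list fell in camera at adjusted p = 0.0310, against adjusted p = 0.267 with an estimated correlation, adjusted p = 0.313 in fry's directional test and adjusted p = 0.0765 in its test for change in either direction. GYS2, the liver glycogen synthase, fell 3.35-fold, from 7387 ± 1348 to 2396 ± 1389 (SD, n = 3 per group), and G6PC1, the catalytic subunit that releases free glucose, fell 2.04-fold, from 15785 ± 2040 to 7844 ± 1827 (SD, n = 3 per group). Each of these passed with limma's p adjusted over the list alone, at adjusted p = 0.00392, and the remaining 11 of the 13 measured genes did not. A second G6PC1 probe set, dimmer than the first, had a log2 difference of -0.13. Camera no longer called the glucose list without vehicle array 1, vehicle array 2 or ligand array 3, at adjusted p = 0.0650, 0.109 and 0.188, or when the spread was modelled without an intensity trend, at adjusted p = 0.0803, or on the mean of a gene's probe sets, at adjusted p = 0.0922, and without vehicle array 2 its median was -0.028.

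In the acute phase list, 2 genes fell with limma's p adjusted over the list alone. SERPINA3, a protease inhibitor that the liver secretes in inflammation, fell 3.6-fold, from 1966 ± 774 to 501 ± 17.8 (SD, n = 3 per group), at limma adjusted p = 0.00259. LBP, which presents bacterial lipopolysaccharide to its receptor, fell 2.53-fold, from 5219 ± 1826 to 1970 ± 125 (SD, n = 3 per group), at limma adjusted p = 0.00319, while a second LBP probe set had a log2 difference of -0.25. HP, the haemoglobin scavenger haptoglobin, had a log2 difference of -0.54 ± 0.26 (SE), or -0.28 without ligand array 1, and did not pass. Of 16 measured genes, 9 were lower and 7 higher, with a median log2 difference of -0.072, and the list did not pass in camera (adjusted p = 0.0896). It passed without vehicle array 1 or vehicle array 2, at camera adjusted p = 0.0294 and 0.0303, but without vehicle array 3 its median was -0.0016, at camera adjusted p = 0.445.

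No member passed in the remaining pathway lists, and camera called none of them. For drug and xenobiotic metabolism, 11 of 17 genes were higher, with a median log2 difference of 0.12 and camera adjusted p = 0.757, and GSTA1, a glutathione transferase, had a log2 difference of 0.55 ± 0.21 (SE). For the unfolded protein response, 8 of 14 genes were higher, with a median log2 difference of 0.0059 and camera adjusted p = 0.757, and SDF2L1, a chaperone component of the endoplasmic reticulum, had a log2 difference of 0.83 ± 0.29 (SE). For the interferon response, 7 of 11 genes were higher, with a median log2 difference of 0.19 and camera adjusted p = 0.362, and MX2, an antiviral GTPase, had a log2 difference of 0.92 ± 0.33 (SE). For the cell cycle, 9 of 11 genes were lower, with a median log2 difference of -0.19 and camera adjusted p = 0.362.

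**Figure D2:**
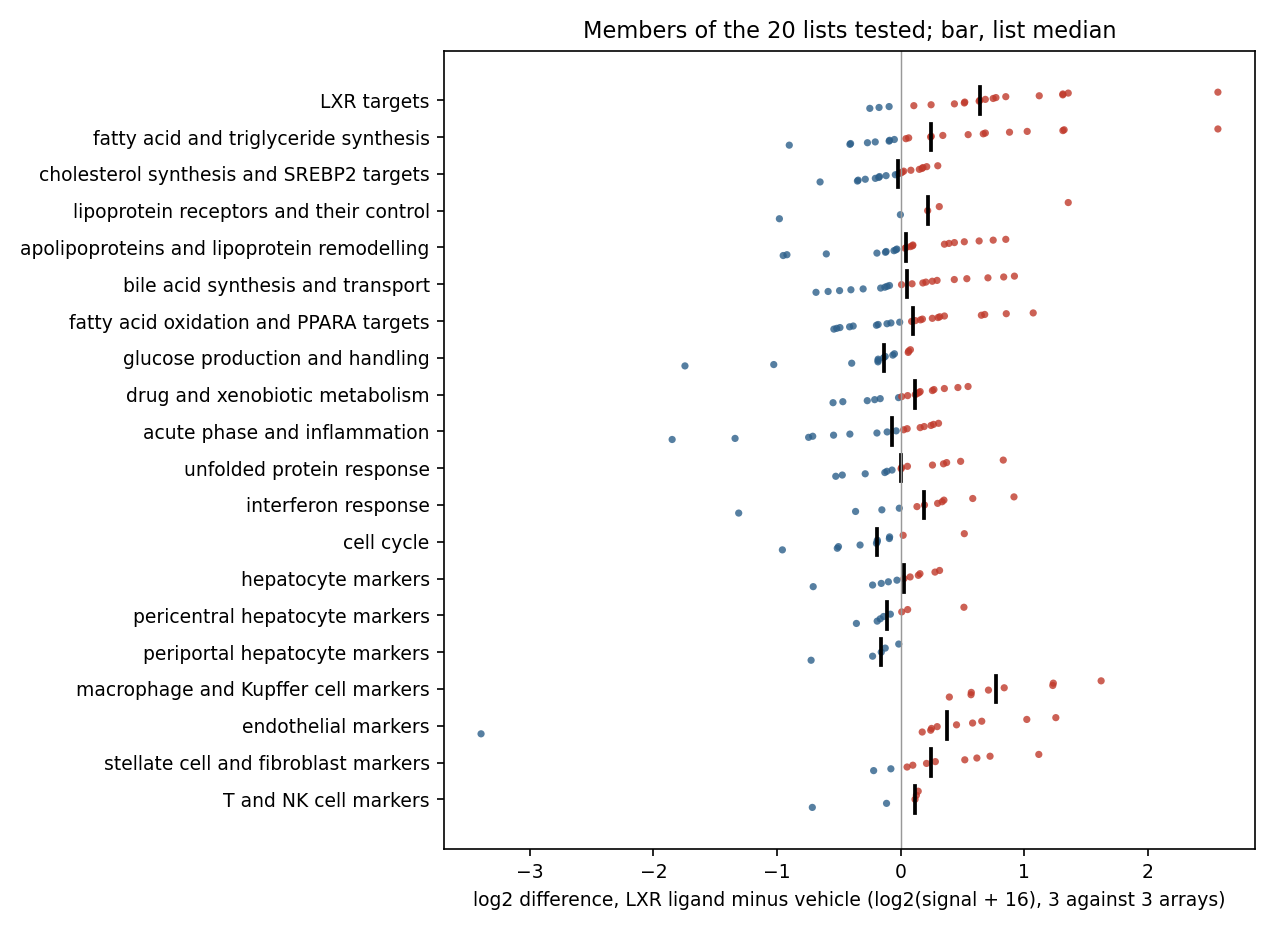
Log2 difference (ligand minus vehicle, on log2(signal + 16), 3 against 3 arrays) of each measured gene in the 20 lists tested, with a bar at the list median. The medians of the LXR targets and of the macrophage markers lie at 0.64 and 0.77, and VWF at -3.39 lies apart from the other endothelial markers.

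A piece of liver holds several cell types, and the markers of macrophages moved with the ligand. MARCO, a scavenger receptor of macrophages, rose 2.35-fold, from 1190 ± 184 to 2816 ± 433 (SD, n = 3 per group). C1QA and C1QB, chains of the first complement component made by macrophages, rose 3.08-fold and 2.36-fold, and C1QC, the remaining chain, rose 1.79-fold. All 8 measured markers of macrophages and Kupffer cells, the resident macrophages of the liver, were higher with the ligand, and the group rose with a median of 1.71-fold. Camera called the list at adjusted p = 1.61e-09, against adjusted p = 0.198 with an estimated correlation, adjusted p = 0.0914 in fry's directional test and adjusted p = 0.0179 in its test for change in either direction. The estimated correlation of these markers was 0.31, far above the preset 0.01. The LXR target group and these markers were thus higher in the same 3 arrays, and how far cell composition bears on the LXR targets was not tested.

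With limma's p adjusted over the list alone, 5 of the 8 macrophage markers passed: MARCO at adjusted p = 0.00172, C1QA at 0.00285, C1QB at 0.0131, C1QC at 0.0146 and CD163, a haemoglobin scavenger receptor named after its values were seen, at 0.0198. On all 5, every ligand array lay above every vehicle array. Without vehicle array 2, MARCO and C1QA were the only 2 of the 8 that passed.

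Endothelial markers were split between a single gene far lower and the rest higher. VWF, the clotting factor made by endothelial cells and platelets, fell 10.5-fold, from 2712 ± 1739 to 230 ± 128 (SD, n = 3 per group), a log2 difference of -3.39 ± 0.47 (SE), at limma adjusted p = 2.33e-04 adjusted over the list alone. The other 9 markers were higher, none passed, and among them LYVE1, a hyaluronan receptor of sinusoidal endothelium, had a log2 difference of 1.02 ± 0.34 (SE), ENG, a coreceptor for growth factors, 0.66 ± 0.23 (SE), and CDH5, the cadherin of endothelial junctions, 0.58 ± 0.23 (SE). The list, with a median log2 difference of 0.37, rose in camera at adjusted p = 0.0312, against adjusted p = 0.601 with an estimated correlation, adjusted p = 0.527 in fry's directional test and adjusted p = 0.0179 in its test for change in either direction. Camera no longer called it without vehicle array 1, vehicle array 2 or ligand array 3, at adjusted p = 0.0733, 0.10 and 0.247, or without the intensity trend, at adjusted p = 0.0750.

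**Figure D3:**
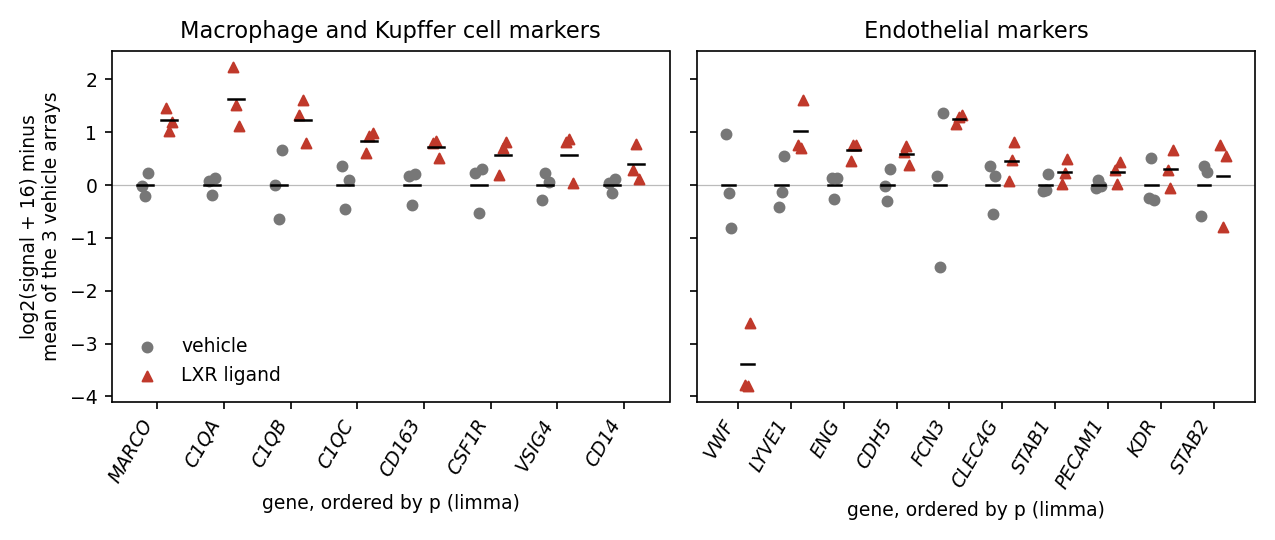
Log2(signal + 16) of each measured macrophage and Kupffer cell marker and each endothelial marker on the 6 liver arrays, relative to the mean of the 3 vehicle arrays, with genes ordered by limma p, circles for vehicle, triangles for the LXR ligand and bars at group means. The 8 macrophage markers have higher means with the ligand, and VWF lies at -3.39 on this scale while the other 9 endothelial markers have higher means.

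In stellate cell and fibroblast markers, COL3A1, a fibrillar collagen chain, rose 2.17-fold, from 4936 ± 1227 to 10982 ± 3640 (SD, n = 3 per group), at limma adjusted p = 0.0284 adjusted over the list alone. Of the 10 measured markers 8 were higher, with a median log2 difference of 0.25, and the list did not pass in camera (adjusted p = 0.0780). It passed without vehicle array 1 or ligand array 1, at camera adjusted p = 0.0461 and 0.00798, with a filter at the 75th percentile, where its median was 0.52, at adjusted p = 0.0311, and on the mean of a gene's probe sets, at adjusted p = 0.0285. Without ligand array 3 its median was 0.11, at camera adjusted p = 0.304. Among hepatocyte markers, products of the main liver cell, 6 of 11 were higher and none passed, with a median log2 difference of 0.028, a mean of -0.020 and camera adjusted p = 0.757 in the upward direction. TF, the iron carrier transferrin, had the smallest p of that list, with a log2 difference of -0.71 ± 0.32 (SE), or -0.33 without ligand array 3, while its other tested probe sets had log2 differences of 0.13 and 0.11.

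Markers of the zones of the liver lobule gave no call. Of 8 pericentral markers 5 were lower, with a median log2 difference of -0.11 and camera adjusted p = 0.757. GLUL, the glutamine synthetase of the cells around the central vein, had a log2 difference of 0.51 ± 0.17 (SE) on its brightest probe set. Of its 3 tested probe sets, 2 were higher and 1 lower. All 5 measured periportal markers were lower, with a median log2 difference of -0.16 and camera adjusted p = 0.190, and that median ran from -0.38 without ligand array 2 to -0.0090 without vehicle array 2. HAL, the histidine ammonia-lyase of that list, had a log2 difference of -0.72 ± 0.29 (SE), or -0.41 without vehicle array 2. The 5 measured markers of T and NK cells had a median log2 difference of 0.12 but a mean of -0.088, and camera gave the downward direction at adjusted p = 0.757. Lists with fewer than 5 measured genes were not tested as lists, and no member of them passed: median log2 differences were 0.086 over 4 cholangiocyte markers, -0.29 over 4 markers of B and plasma cells, -0.12 over 4 markers of neutrophils and monocytes, and -1.24 over 2 red blood cell markers. HBB, the beta chain of haemoglobin, had a mean signal of 4389 ± 5802 with vehicle and 691 ± 150 with the ligand (SD, n = 3 per group), with overlapping groups. Vehicle array 1 carried most of that difference, and so weighs on the red blood cell median: its HBB signal was 11085, against 1255 and 828 on vehicle arrays 2 and 3, and without it the log2 difference was -0.57 instead of -1.71.

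Over all 27304 tested probe sets, the genes with the smallest p included both LXR targets and genes of other pathways, and none passed the adjusted threshold. Higher with the ligand were GALNS, a lysosomal sulfatase, with a mean signal of 93.7 ± 17.9 with vehicle and 554 ± 104 with the ligand (SD, n = 3 per group), and SNAI2, a transcriptional repressor of epithelial genes, with 202 ± 16.3 and 856 ± 294. Lower with the ligand were EGR1, an immediate early transcription factor, with 4228 ± 408 with vehicle and 1536 ± 182 with the ligand (SD, n = 3 per group), and GPX3, a secreted glutathione peroxidase, with 7808 ± 431 and 3048 ± 1091. SULT1A1, a sulfotransferase of phenols, had 19842 ± 1429 with vehicle and 36178 ± 1013 with the ligand.

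In limma with Benjamini-Hochberg adjustment, 0 probe sets had an adjusted p under 0.05, the lowest being 0.319. At an unadjusted p under 0.05 there were 1523 probe sets, 886 higher and 637 lower with the ligand, where 1365 were expected by chance, and no other tool was run for single probe sets. In the simulated data, 5.34% of unchanged probe sets had such a p, above the share of 0.05 behind that expectation. The simulation took estimated SDs as true, which may itself move that share. The groups did not overlap for 1636 probe sets with higher and 1354 with lower signals, 11.0% of those tested, against the 10% that chance gives for 3 against 3. Leaving out vehicle array 2 gave 1 call, ACAA2, an enzyme of fatty acid oxidation, at limma adjusted p = 0.00387, and leaving out ligand array 2 gave 1, SREBF1 at limma adjusted p = 0.0453.

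The 10 named probe sets with the smallest p and higher signals with the ligand had log2 differences of 0.87 to 2.98, and the 10 lower ones -3.39 to -1.07. None of these 20 passed with adjustment over all probe sets, with the lowest limma adjusted p at 0.319 for EGR1 and VWF. Besides SREBF1, ABCG1, MARCO, GALNS, SNAI2 and SULT1A1, the higher ones were FCGR1BP, an Fc receptor pseudogene (2.98), LINC02593, a long noncoding RNA (2.35), COL1A1, a fibrillar collagen chain (1.64), and PHKG2, the catalytic subunit of liver phosphorylase kinase (1.13), given as log2 differences. FCGR1BP is close in sequence to the functional Fc receptor genes, so the transcript behind its signal is uncertain. Mean signals with vehicle were 28.5 for FCGR1BP, 79.0 for LINC02593 and 93.7 for GALNS, and with the ligand 82.2 for KIF25, all under the filter value of 129 and not shown to lie above background, so the sizes of these 4 log2 differences depend on the pseudocount and on that background. The brightest COL1A1 probe set had a log2 difference of -0.22. Besides VWF, SERPINA3, LBP, EGR1 and GPX3, the lower ones were KIF25, a kinesin (-2.33), COX2, a mitochondrially encoded subunit of cytochrome c oxidase (-2.03), FETUB, a liver protease inhibitor (-1.88), KMO, a hydroxylase of the kynurenine pathway (-1.12), and INSR, the insulin receptor (-1.07), given as log2 differences. The second tested probe sets of KIF25 and COX2 had log2 differences of -0.44 and -0.14, and the other tested INSR probe sets -0.27, -0.46 and -0.34. Of the 3 tested KMO probe sets, 2 were lower and 1 higher. All 3 EGR1 probe sets were lower, at -1.45, -1.47 and -0.85.

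RNA quality was compared through the log2 ratio of the 3' to the 5' control probe sets, which grows as RNA degrades. For GAPDH it was 1.54 ± 0.46 with the ligand and 1.34 ± 0.35 with vehicle (SD, n = 3 per group; exact two-sided permutation p = 0.6), and for ACTB 3.09 ± 0.79 and 2.57 ± 0.46 (SD, n = 3 per group; exact two-sided permutation p = 0.4). The smallest p that 3 against 3 arrays allow is 0.1, so the design could not reach 0.05, and the ranges of both groups overlapped. Ligand array 3 had the highest ratio for both controls. It was 2.05 for GAPDH against 0.991 to 1.70 on the other arrays, and 4.0 for ACTB against 2.15 to 3.06. Without that array camera no longer called the glucose and endothelial lists. The same held without vehicle array 1, which had the lowest ratio for both controls, and without vehicle array 2.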

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

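The LXR list without SREBF1, ABCG1 and MYLIP, the macrophage list without MARCO and C1QA and the endothelial list without VWF, each with the preset and an estimated correlation, were chosen after the results were seen, and the other alternatives before. Median log2 differences of these reduced lists were 0.58, 0.64 and 0.45, and camera called each at the preset correlation, at adjusted p = 3.30e-04, 8.11e-06 and 1.97e-04, and none with an estimated correlation, at adjusted p = 0.198, 0.277 and 0.257. Over all alternatives the adjusted p ran from 5.22e-09 to 0.198 for the LXR list, from 4.19e-10 to 0.277 for the macrophage list, from 0.00643 to 0.313 for the glucose list and from 1.97e-04 to 0.601 for the endothelial list. Of 955 values recomputed for 58 named genes, 949 kept their direction and their side of the threshold, 5 reversed and 1 newly passed. None of these genes passed over all probe sets in the main fit, so keeping their side meant still not passing. Genes with non-overlapping groups cannot reverse when 1 array is left out, so the 949 is no measure of robustness. Causes were not tested, except that filters and 1 probe set per gene change how many probe sets are tested. Robust eBayes was run for probe sets and not for lists, since camera has no such option. MAS5 detection calls were not used, so how far signals lie above background limits the dim probe sets in an unknown way.

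In limma the count of probe sets past the adjusted threshold was 0, as under every alternative using all 6 arrays, and the 1523 at an unadjusted p under 0.05 became 2891 with no filter, 871 with a filter at the 75th percentile and 806 with 1 probe set per gene. Camera's calls, 2 pathway lists and 2 cell type lists, became 1 and 1 without the intensity trend, where the LXR and macrophage lists stayed. On the mean of a gene's probe sets, 1 pathway list and 3 cell type lists were called. With an estimated correlation 0 and 0 lists passed, and in fry's directional test 0 and 0, each with 3 lists at an unadjusted p under 0.05: the LXR median of 0.64 and the macrophage median of 0.77 stand unchanged there, at adjusted p = 0.198 for both with an estimated correlation and 0.0914 for both in fry.

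So few arrays cannot show whether replicate numbers pair animals. Same-numbered arrays' deviations from group means correlated at r = 0.040, -0.031 and 0.070. Ligand arrays 1 and 3, not 2, matched their own number best. With the replicate number as a block, limma called 0 probe sets, with 1707 at an unadjusted p under 0.05, camera called 2 pathway and 3 cell type lists (stellate cell markers added, adjusted p = 0.0286), and 5 LXR targets passed over the list alone, ABCA1 and PLTP added.

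Leaving out each array in turn gave 0 to 1 probe sets, 1360 to 1556 at an unadjusted p under 0.05, 1 to 3 pathway lists, 1 to 3 cell type lists, LXR medians of 0.49 to 0.80, macrophage medians of 0.65 to 0.91, 3 to 8 LXR targets (8 without vehicle array 3) and 2 to 7 macrophage markers (2 without vehicle array 2). Without ligand array 3, 1 pathway and 1 cell type list were called, and without vehicle array 2, 1 cell type list. Medians of lists that camera did not call crossed 0: fatty acid synthesis -0.054 to 0.44, cholesterol synthesis -0.072 to 0.046, apolipoproteins -0.031 to 0.10, bile acids -0.18 to 0.15, fatty acid oxidation -0.059 to 0.20, drug metabolism -5.52e-04 to 0.22, unfolded protein response -0.031 to 0.071, interferon response -0.061 to 0.29, hepatocytes -1.73e-04 to 0.070, pericentral -0.21 to 0.034, and T and NK cells -0.35 to 0.22. NR1H3 ran from -0.044 to 0.31. Among lists that kept their sign, periportal medians ran from -0.38 to -0.0090, acute phase medians from -0.11 to -0.0016, stellate medians from 0.11 to 0.45, cell cycle medians from -0.26 to -0.061, medians of lipoprotein receptors from 0.077 to 0.28, endothelial medians from 0.21 to 0.49 and glucose medians from -0.24 to -0.028. Of the named genes, those besides NR1H3 that moved by over 1.5 times were ABCA1 (0.48 to 0.97), ABCG5 (0.21 to 0.76), ABCG8 (0.39 to 1.53), CETP (0.39 to 0.80), SCD (0.51 to 2.04), CYP8B1 (-0.64 to -0.33), GSTA1 (0.33 to 0.69), TM7SF2 (-0.53 to -0.24), HP (-0.79 to -0.28), HAL (-0.91 to -0.41), TF (-0.99 to -0.33), HBB (-2.43 to -0.57) and JUNB (-0.92 to -0.42).

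Other reversals were the unfolded protein response at -0.037 and hepatocyte markers at -0.016 under median centring, cholesterol synthesis at 0.0082 with array weights, and lipoprotein receptors at -0.0078 and fatty acid oxidation at -0.090 on the mean of a gene's probe sets. The other tested probe set of SREBF1, FASN and LPIN1 had a log2 difference of -0.60, -0.22 and 0.14, and the 2 others tested for TF had a median of 0.12.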

Other observations

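The comparisons of macrophage markers with those of other cell types, of VWF with the other endothelial markers and with its other probe set, the limit of 259 on mean signal and the counts over other splits of the arrays were chosen after the results were seen. The second macrophage, platelet and large vessel, and immediate early lists were fixed after the patterns were seen and before the values of their lists were. A list of insulin responsive genes was also fixed then, after INSR, GYS2 and G6PC1 had been seen. It holds INSR itself, on another probe set, and IRS2, IGFBP1 and PDK4 of the earlier lists. That list was therefore not independent of values already seen.

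The insulin responsive genes gave no call. All 10 were measured, 4 higher and 6 lower with the ligand, none passed with limma's p adjusted over the list alone, and their mean log2 difference was -0.10 with a 95% interval from -0.75 to 0.54. The list's median was -0.14, and camera gave adjusted p = 0.224 over the 4 added lists. The immediate early genes other than EGR1 held a single call: MYC, a transcription factor of growth, fell 2.05-fold, from a mean signal of 3134 ± 597 to 1564 ± 514 (SD, n = 3 per group), at limma adjusted p = 0.0364 adjusted over the list alone.

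Macrophage markers were higher with the ligand, and a candidate explanation is a larger share of macrophage RNA in the tissue. A second list of macrophage genes, none of them in the first, had 13 of 13 measured genes higher, among the brightest LAPTM5 at 1704 ± 564 with vehicle and 2978 ± 762 with the ligand and FCER1G at 1737 ± 790 and 2851 ± 250 (SD, n = 3 per group). Its mean log2 difference was 0.64, but the 95% interval ran from -0.055 to 1.33 and 0 of the 13 passed in limma over the list alone, with 4 at an unadjusted p under 0.05 and camera adjusted p = 1.00e-06 (adjusted p = 0.303 with an estimated correlation), so the test does not decide. A lower share of hepatocytes would raise the markers of other cell types alike and lower those of hepatocytes. The 11 hepatocyte markers had a mean log2 difference of -0.020 (95% interval -0.25 to 0.21), which leaves a small fall possible. The 9 endothelial markers without VWF were all higher, with a mean log2 difference of 0.55. Of 10 stellate cell markers 8 were higher, with a mean of 0.33. Of 9 lymphocyte markers 5 were higher, with a mean of -0.15, and the macrophage mean exceeded theirs by 1.05 (95% interval 0.82 to 1.29). Only 3 of those 9 lymphocyte markers reached a mean signal of 259, so they exclude nothing. The macrophage mean of 0.90 exceeded that of the 25 markers of other cell types, VWF and red blood cells aside, with a mean signal of at least that, 2 times the filter value, by 0.63 (95% interval -0.016 to 1.28), so a lower hepatocyte share, more macrophages and an action of the ligand on these genes inside macrophages, which was not tested, cannot be told apart here without cell counts.

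VWF was lower with the ligand by -3.39 on the log2 scale. Fewer endothelial cells would lower the other 9 endothelial markers too, and their mean log2 difference was 0.55 (95% interval 0.0046 to 1.09). Fewer platelets or large vessels cannot be told apart from lower expression: 10 measured genes of that list had a mean log2 difference of 0.19 (95% interval -0.26 to 0.64), with 6 higher and 4 lower, but only 3 reached a mean signal of 259, so the bound of -1 set beforehand was wrong for genes too dim to show a fall. A sequence difference between animals under the human probes cannot be told apart from lower expression, since the only other VWF probe set, at a log2 difference of -0.15, was too dim to be tested. An effect of the ligand on VWF itself stays open and was not tested.

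EGR1 was lower with the ligand on all 3 of its probe sets, and differences in the handling of tissue move immediate early genes together. The other 9 measured immediate early genes, of 14 listed, had a mean log2 difference of -0.16 (95% interval -0.40 to 0.088), above the bound of -0.5 set beforehand. That argues against a common fall as large as that bound, while a smaller common fall is not excluded. Their median was -0.056, 6 of the 9 were lower and 3 higher, and camera gave adjusted p = 0.224. Beside the fall of MYC, JUNB had a log2 difference of -0.73 ± 0.33 (SE) and JUN -0.44 ± 0.20 (SE). A handling difference that moves only some of these genes is therefore not excluded. An effect of the ligand on EGR1 stays open and was not tested.

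The 6 arrays can be split into 3 and 3 in 10 ways, the real split included, which is too few for a share under 0.05. In limma the real split gave 0 probe sets past the adjusted threshold, with 1523 at an unadjusted p under 0.05, and the highest of the other splits gave 0, with 1636 unadjusted at most. With a real count of 0, all 10 of 10 are as large whatever the data, so that count tells nothing. For pathway lists called by camera, the real split gave 2 and the highest other 5, with 4 of 10 as large; the 5 came from setting vehicle arrays 1 and 2 and ligand array 2 against the rest. For cell type lists the real split gave 2 and the highest other 2, with 3 of 10 as large. The mean log2 difference of the LXR targets was 0.70 in the real split and 0.42 at most in the others, with 1 of 10 as large, and that of the macrophage markers 0.90 and 0.58, with 1 of 10 as large. At the preset correlation, camera's unadjusted p for the LXR list was 3.65e-09 in the real split and 3.53e-04 at least in the others. For the macrophage list it was 8.06e-11 and 1.94e-05, so small camera p-values also arose in splits other than the real one.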
